A study of Mus musculus with 2 samples.

How the data were processed

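The series holds 2 mouse samples, 1 per treatment: nuclei of hindbrain neurons that project to the lumbar cord and were active in a hot water bath or in the condition labelled SNI with brush. Per the labels, hindbrains of the same treatment were pooled, nuclei were sorted by fluorescence and libraries were made with the 10x 3' kit. Each sample has a table of UMI counts per gene and nucleus, deposited by the authors, with a gene list and a barcode list. The values are whole numbers and were used as raw counts. Per the submitters' processing notes, Cell Ranger 5.0, Seurat (version not given in the sources used here) and the mm10 genome were used. The barcode lists hold 723 and 850 barcodes, of which 425 and 288 have a column in the count tables, so the authors' filter on nuclei came before deposit. Its rule is not given in the sources used here.

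The tables share 23912 genes. Per library, 16344606 and 11298755 UMIs were counted. Nuclei were kept with at least 500 genes and under 5% mitochondrial UMIs, which removed none, and doublets called by Scrublet per library were removed, 2 in each. Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes were chosen within libraries, each gene was centred within its library, and Leiden clustering was run on 30 principal components with 15 neighbours at resolution 1.0 (scanpy 1.11.5, anndata 0.12.19, python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9).

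Cell type markers, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The scoring of clusters was set afterwards. A cluster with at least 3 markers of a special class among its 10 leading genes took that name. Other clusters were neuronal where at least 3 of 8 neuron markers reached 0.5 times the level over all nuclei, glutamatergic-like with at least 75% of transmitter UMIs from vesicular glutamate transporters and inhibitory-like with at most 25%. The rule was changed after its first result had been seen: in the second version, a cluster with more markers of another class than of its own among its leading genes lost its transmitter name, with V2a-type markers not counted against a glutamatergic name. This took 1 cluster out of the glutamatergic-like class, and the first version is kept as an added alternative.

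Shares carry exact Clopper-Pearson 95% intervals. For expression, counts were summed over nuclei per library and given as CPM with exact Poisson intervals. Ratios are log2 of SNI with brush over hot water bath with 0.5 UMI added to both, and their intervals are exact, conditional on the summed count. All intervals cover counting error only. Where a count is 0, the limit given is 3 counts of the total. Nuclei are not replicates, so no p-value was computed. Named genes needed at least 100 UMIs over both libraries and a UMI in at least 10 nuclei of the higher library. At most 25% of a gene's UMIs in that library could come from 1 nucleus. Predicted gene models, mitochondrial and ribosomal protein genes, Xist, Tsix and 4 Y-linked genes were left out, whereas other X-linked genes were kept. The 12 highest and 12 lowest ratios were taken. Within each class the floor was 50 UMIs and 5 genes were taken each way. Within lists, members with at least 20 UMIs whose interval excluded a ratio of 1 were named, at most the 4 with the largest ratios; some of these are given in the text, and transmitter, monoamine and opioid genes are given whatever their value. Genes named outside this rule, such as Fos, Rarres2 and those given within serotonergic nuclei, were chosen after their values were seen. Some genes that the rule names are not reported here. A list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries only. For lists matched on length too, 10 bins of length were crossed with 10 of expression. Gene positions come from GENCODE vM21 for mm10, in which all 58 identifiers looked up were found, and gene lengths from the same annotation cover 99.9% of the 17479 genes with at least 20 UMIs.

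On simulated data with 200 changed genes among 12981, genes raised 4-fold in the neuron comparison gave a median log2 ratio of 2.00 and genes lowered 4-fold gave -1.95. For genes changed 2-fold the medians were 1.00 and -0.96. The intervals held the true ratio for 95.2% of unchanged genes. The simulated sums were independent Poisson counts, the model behind the intervals, without variation between nuclei, so this checks the computation only. Of 1000 unchanged lists of 20 genes, 94.8% lay within the central 95% of the random lists; a first run with 100 such lists had placed all of them there, and the number was raised for that reason. Alternatives tried were other filters, doublets kept, resolutions of 0.5 and 2.0, 15 components, no centring, separate clustering, class by nucleus, other thinned depths, size-factor scaling, means over nuclei, 2 added UMIs and other floors for lists. Added after seeing the data were thinning to 9000 UMIs, the 75% rule per nucleus, the first naming rule and nuclei with at most 0.5% mitochondrial UMIs. Barcodes without a column in the count tables were not analysed here.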

Results

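Nuclei of descending hindbrain neurons were sequenced from mice of the TRAP2 line, in which neurons active during a chosen time window can be marked by recombination. A retrograde virus placed in the lumbar cord marked neurons that project there with a nuclear fluorescent protein, and marked nuclei were sorted before droplet capture. The labels name 2 treatments, a hot water bath and SNI with brush, and give 1 pooled library for each. No replicate exists for either treatment, so no test between treatments was made. All intervals below are exact 95% intervals that cover counting error within each library only, and every ratio compares these 2 libraries, not the treatments at large.

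The hot water bath library held 425 nuclei and 16344606 UMIs (unique molecular identifiers, the counted transcripts), with a median of 36962 UMIs and 7194 genes per nucleus. The SNI with brush library held 288 nuclei and 11298755 UMIs, with a median of 32852 UMIs and 7460 genes. Mitochondrially encoded genes took 0.148% of all UMIs in the hot water bath library and 0.514% in the SNI with brush library. Gm42418, a gene model that overlaps ribosomal RNA, took 0.235% and 0.958%. After removal of 2 called doublets per library, 423 and 286 nuclei were clustered together.

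The first question was which kinds of cell the sorted nuclei came from. All 423 hot water bath nuclei and 269 of the 286 SNI with brush nuclei lay in neuronal clusters, which is 100% (interval 99.1 to 100%) and 94.1% (90.7 to 96.5%). The other 17 nuclei, 5.94% of that library (3.50 to 9.35%), formed an unnamed cluster led by liver genes such as Cps1 and Alb. No hot water bath nucleus fell in that cluster, which allows a share of up to 0.709%. Of the 19 neuronal clusters, 11 were glutamatergic-like, 2 inhibitory-like and 1 serotonergic neuron-like, and 5 stayed without a transmitter name. None was led by noradrenergic markers.

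Glutamatergic nuclei made up more of the hot water bath library and inhibitory nuclei more of the SNI with brush library. Glutamatergic-like clusters held 276 of 423 neuronal nuclei after the hot water bath (65.2%, interval 60.5 to 69.8%) and 61 of 269 in the SNI with brush library (22.7%, 17.8 to 28.2%). Inhibitory-like clusters held 9.93% (7.25 to 13.2%) and 27.9% (22.6 to 33.6%). Serotonergic neuron-like nuclei, which express the serotonin synthesis enzyme Tph2, numbered 30 (7.09%, 4.84 to 9.97%) and 4 (1.49%, 0.407 to 3.76%). Clusters without a transmitter name took 17.7% (14.2 to 21.7%) and 48.0% (41.9 to 54.1%). Among the latter, 1 cluster led by the oligodendrocyte marker St18 but with 94.2% of its transmitter UMIs from vesicular glutamate transporters, held 3.55% and 0.372% of neuronal nuclei.

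Over all neuronal nuclei, assigning each nucleus by its own transmitter UMIs kept the direction of both shares. With at least 75% of 3 or more transmitter UMIs of one kind, a rule added after seeing the data, glutamatergic nuclei made up 59.8% (55.0 to 64.5%) after the hot water bath and 45.7% (39.7 to 51.9%) in the SNI with brush library. Inhibitory nuclei made up 19.9% (16.2 to 24.0%) and 39.0% (33.2 to 45.1%). By this rule, serotonergic neuron-like nuclei can count as inhibitory. All 30 in the hot water bath library held Gad2 UMIs, and only 2.41% of their cluster's transmitter UMIs came from vesicular glutamate transporters. Over both libraries, 1940 Tph2 UMIs lay in nuclei inhibitory by this rule. With UMIs of one kind only, a rule set before the data were seen, the glutamatergic shares were 54.6% and 26.8% and the inhibitory shares 14.4% and 31.2%. Within subsets the 75% rule gave a weaker glutamatergic difference. Among nuclei with at most 0.5% mitochondrial UMIs the intervals overlapped, at 60.5% (55.6 to 65.3%) and 50.3% (43.0 to 57.6%). In nuclei with Y-linked UMIs the shares were 46.8% and 49.0%. The cluster-based inhibitory share did not keep its direction at a clustering resolution of 0.5, where it was 3.31% in the hot water bath library and 0.743% in the SNI with brush library. Most inhibitory-like nuclei, 28 of 42 and 73 of 75, came from a cluster led by mitochondrially encoded genes together with Gad1, and a cluster found mostly in 1 library may mark that library rather than a type.

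**Figure D1:**
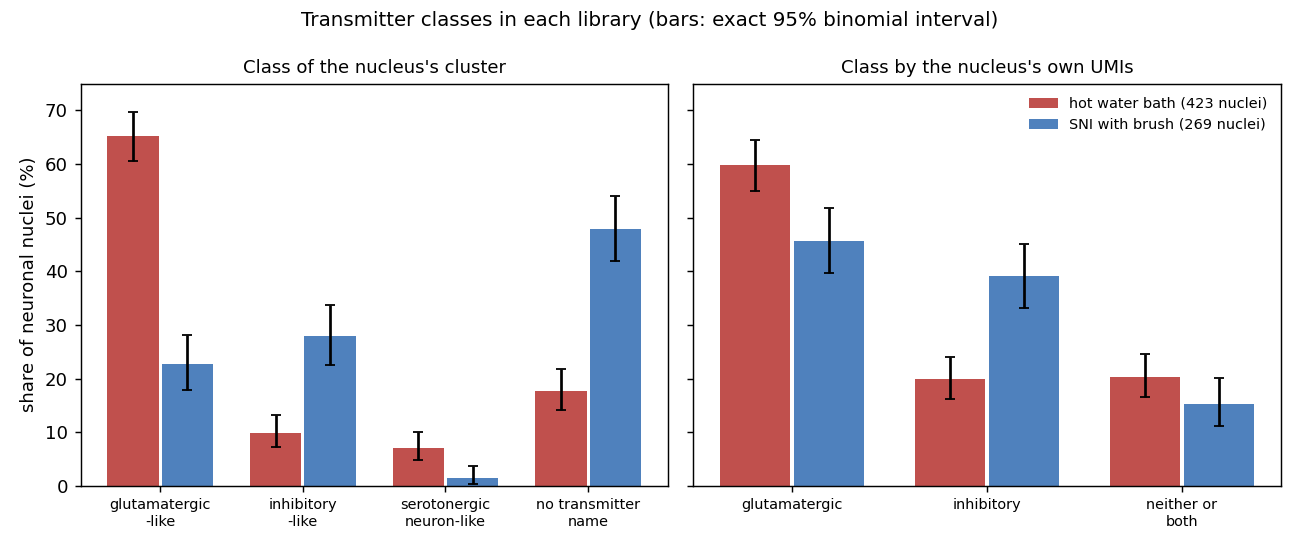
Share of neuronal nuclei (percent, from 0) in each transmitter class for the hot water bath library (red, 423 nuclei) and the SNI with brush library (blue, 269 nuclei), with exact 95% binomial intervals. Left, by cluster, where glutamatergic-like nuclei made up 65.2% and 22.7%; right, by each nucleus's own transmitter UMIs, where they made up 59.8% and 45.7%.

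Most glycine and GABA genes were higher in the SNI with brush library. Slc6a5, the neuronal glycine transporter (ENSMUSG00000039728, chromosome 7, 49910146 to 49963856, mm10), stood at 11.3 CPM (counts scaled to a total of 1000000 UMIs) in hot water bath neurons and 80.5 CPM in SNI with brush neurons, a log2 ratio of 2.83 (2.60 to 3.07). Slc32a1, the vesicular transporter of GABA and glycine (ENSMUSG00000037771, chromosome 2, 158610767 to 158615748), had a log2 ratio of 2.09 (1.86 to 2.34). The GABA synthesis enzyme Gad1 had 1.14 (0.92 to 1.36), whereas Gad2 had 0.15 (0.02 to 0.28) and turned to -0.094 under size-factor scaling. Within inhibitory-like nuclei Gad1 and Gad2 had -0.15 and -0.64. Slc17a6, the main vesicular glutamate transporter of the brainstem (ENSMUSG00000030500, chromosome 7, 51622006 to 51671119), was level at 121.4 and 121.1 CPM, a log2 ratio of 0.00 (-0.11 to 0.10). Slc17a7 and Slc17a8 were higher in the SNI with brush library, with log2 ratios of 2.07 (1.65 to 2.52) and 1.39 (0.69 to 2.14).

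Shares of nuclei with a UMI gave the same order for the inhibitory genes. After thinning each nucleus to 1000 UMIs, which left out none, Slc6a5 was seen in 0.946% (0.258 to 2.40%) of hot water bath neurons and 9.67% (6.41 to 13.8%) of SNI with brush neurons. Slc32a1 was seen in 1.65% (0.668 to 3.38%) and 5.58% (3.15 to 9.03%), and Slc17a6 in 12.1% (9.11 to 15.5%) and 10.0% (6.72 to 14.3%). At 9000 UMIs, a depth added after seeing the data, Slc6a5 was seen in 5.67% and 27.5% and Slc17a6 in 59.8% and 46.1%. Unthinned, Slc6a5 was seen in 11.1% and 40.5%. In glutamatergic-like nuclei, which should lack Slc6a5, the unthinned shares were 7.25% and 13.1% at median depths of 38370 and 36048 UMIs, against 36962 and 32891 UMIs over all neurons.

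**Figure D2:**
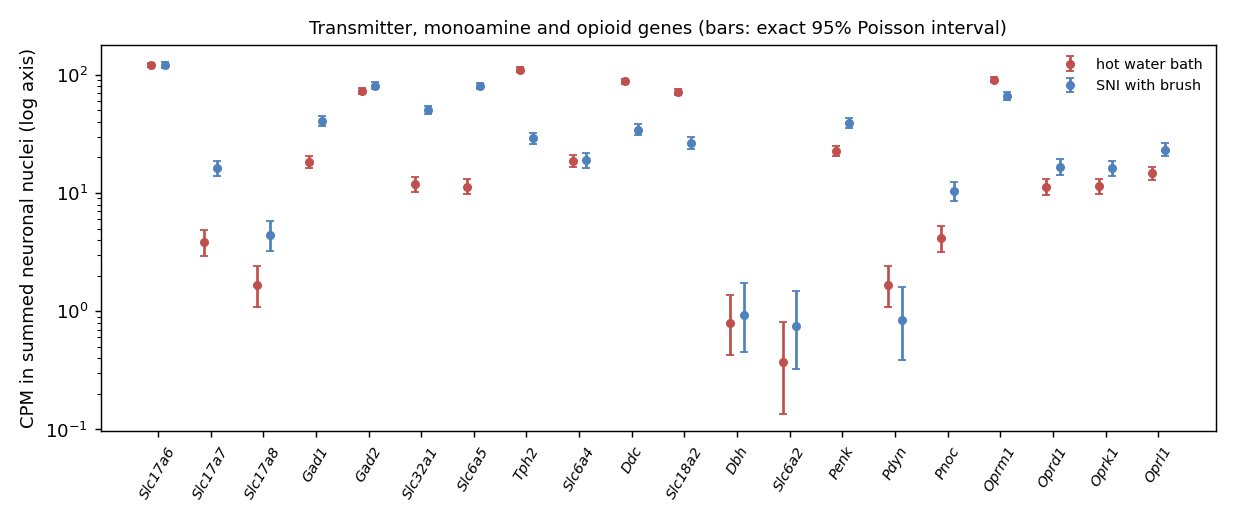
CPM (log axis) of transmitter, monoamine and opioid genes in counts summed over neuronal nuclei of the hot water bath library (red) and the SNI with brush library (blue), with exact 95% Poisson intervals. Slc6a5 stands at 11.3 and 80.5 CPM, Slc17a6 at 121.4 and 121.1 CPM and Tph2 at 110.2 and 29.0 CPM.

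Serotonergic genes were lower in the SNI with brush library. Tph2 (ENSMUSG00000006764, chromosome 10, 115078641 to 115185022) stood at 110.2 and 29.0 CPM, a log2 ratio of -1.93 (-2.11 to -1.75). Maob, which degrades monoamines, had -1.87 (-2.24 to -1.53), the vesicular monoamine transporter Slc18a2 had -1.43 (-1.63 to -1.24) and the decarboxylase Ddc had -1.36 (-1.53 to -1.20). The serotonin transporter Slc6a4 was level at 0.01 (-0.25 to 0.27). Of the 9 measured genes of the serotonergic list, 6 were at least 1.5-fold lower and 1 at least 1.5-fold higher, and the median of -0.78 lay at percentile 0 of 10000 random lists matched on expression. Within serotonergic neuron-like nuclei Tph2 stood at 1323 CPM (1262 to 1386) in 30 hot water bath nuclei and 1753 CPM (1558 to 1966) in 4 SNI with brush nuclei.

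Noradrenergic genes were scarce in both libraries. Dbh, the enzyme that makes noradrenaline, gave 13 and 10 UMIs in all neurons, at 0.801 and 0.934 CPM, and the noradrenaline transporter Slc6a2 gave 6 and 8. Their log2 ratios were 0.24 (-1.13 to 1.53) and 0.99 (-0.70 to 2.82). At this depth no difference between the libraries was detectable in Dbh or Slc6a2. Th gave 21 and 26 UMIs, a log2 ratio of 0.90 (0.02 to 1.81). Of the 7 measured genes of the noradrenergic list, 4 were at least 1.5-fold lower and 2 at least 1.5-fold higher, the highest at 3.10. The noradrenergic list had a median of -0.59, and its lowest members, Slc18a2 and Ddc, are also serotonergic; with genes of 5 or more UMIs admitted it was 0.24.

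Among opioid genes, the peptide precursors Penk and Pnoc were higher in the SNI with brush library, with log2 ratios of 0.77 (0.57 to 0.98) and 1.32 (0.88 to 1.79). Within classes the direction was mixed: Penk had 2.39 in glutamatergic-like and -0.66 in inhibitory-like nuclei, and Pnoc had -0.41 and 0.88. The mu receptor gene Oprm1 (ENSMUSG00000000766, chromosome 10, 6758506 to 7038198) was lower, at 90.9 and 66.0 CPM and a log2 ratio of -0.46 (-0.59 to -0.33). The delta, kappa and nociceptin receptor genes Oprd1, Oprk1 and Oprl1 had 0.56, 0.50 and 0.67, each with an interval above 0. Pdyn had -0.93 (-2.26 to 0.15) from 27 and 9 UMIs, and Pomc 0.60 (-0.13 to 1.33). The list of 8 genes had a median of 0.58 and lay at percentile 84.7.

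The next comparison covered all genes in summed neuronal nuclei. Over the 12981 genes with at least 100 UMIs the log2 CPM of the 2 libraries correlated across genes at Pearson r = 0.944, where genes are not independent replicates, and the median absolute log2 ratio was 0.35. Scaling by median-of-ratios size factors instead of total UMIs shifts every log2 ratio by -0.24, and list medians under that scaling are given where the sign turns. Ratios also followed gene length: the median log2 ratio was 0.64 in the shortest of 5 equal groups of genes and -0.05 in the longest. For some lists the percentile is therefore also given among random lists matched on both length and expression, an addition made after seeing the data.

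The 12 genes with the highest ratios included Ttr, the thyroid hormone carrier of choroid plexus and liver, at 9.61 CPM in hot water bath neurons and 232 CPM in SNI with brush neurons (log2 ratio 4.59, 4.36 to 4.84). Ttr was seen in 267 of the 269 SNI with brush neurons and 116 of the 423 hot water bath neurons, and also in all 17 liver-gene nuclei at 2108 CPM, so its share of nuclei does not separate expression in neurons from free RNA. Apoa1, an apolipoprotein of liver, had 3.62. Olfr1124, the short neuronal RNA Bc1, Atp13a5, Bmp6, Ptprq, Stxbp2, Cd163l1 and Snhg9 had between 3.17 (Snhg9) and 4.33 (Olfr1124). The transcription factor Foxp2 had 3.42 (3.11 to 3.76) and was seen in 47 of the 269 SNI with brush neurons, and the natriuretic peptide Nppc had 3.15 (2.62 to 3.76).

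The 12 lowest were led by Gcg, which encodes proglucagon, the precursor of a peptide of the caudal brainstem. It stood at 67.6 and 7.19 CPM (log2 ratio -3.22, -3.58 to -2.90) and was seen in 34 and 2 neurons. Cpa6 had -2.29 (-2.45 to -2.13), with -3.71 in inhibitory-like nuclei but a higher level in the SNI with brush library in glutamatergic nuclei (0.76 by own UMIs under the 75% rule). Svep1, Gna14, Prdm6, Tex47, Gucy2f, Catspere1, Lama3 and Onecut3 lay between -2.18 (Svep1) and -1.76 (Onecut3), and Tph2 and Maob completed the group. Catspere1 is annotated as a pseudogene, so its counts may be shared with a related copy.

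Within glutamatergic-like nuclei the highest ratios included those of Ttr (4.49), Atp13a5 (3.93), Cd163l1 (3.56) and Pax6 (3.47). The lowest belonged to Gna14 (-2.83), Crhbp (-2.64), Catspere1 (-2.60), Tex47 (-2.52) and Tctex1d1 (-2.47), each with between 2 and 7 SNI with brush UMIs. The main glutamatergic-like clusters differed between libraries: a Prdm6 and Crh cluster held 56 of 276 hot water bath nuclei, and a Slc17a7 and Col27a1 cluster held 20 of 61 SNI with brush nuclei. Within inhibitory-like nuclei Ttr (6.03), Sox6 (5.92), Atp13a5 (4.85), Bc1 (4.46) and Phpt1 (3.38) were highest. Sox6, Atp13a5 and Bc1 rested on 1 hot water bath UMI each, Phpt1 on 4 and Ttr on 5. Their sizes and order are therefore uncertain, with an interval of 4.00 to 11.8 for Sox6. Adamts12 (-4.18), Cpa6 (-3.71), Pdgfd (-3.69), Lmx1b (-3.30) and Kcnq5 (-2.55) were lowest, and 14 of the 42 hot water bath nuclei of this class came from the Adamts12 and Penk cluster, against 2 of 75 in the other library.

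Hox genes and regional transcription factors were higher in the SNI with brush library. All 11 measured Hox genes of paralog groups 4 to 8, which mark the caudal hindbrain and cord, were at least 1.5-fold higher, with a median log2 ratio of 1.87 at percentile 100, also when length was matched. Hoxb5 (ENSMUSG00000038700, chromosome 11, 96303336 to 96306121) had 2.62 (2.15 to 3.15) and Hoxb6 had 2.24 (1.67 to 2.88). Within glutamatergic-like and inhibitory-like nuclei the list medians were 1.26 and 0.86. For the more rostral groups 1 to 3, 4 of 5 genes were at least 1.5-fold higher with a median of 1.08. Of 36 hindbrain domain factors 21 were at least 1.5-fold higher and 6 at least 1.5-fold lower, and Foxp2 and En1 (3.02) were among the highest. Their median of 1.16 was -0.12 within glutamatergic-like and 0.94 within inhibitory-like nuclei, and -0.15 over members with at least 100 UMIs.

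Genes of oxidative phosphorylation, the mitochondrial energy pathway, were higher in the SNI with brush library: 19 of 21 by at least 1.5-fold and none lower by that much. Ndufa5 had 2.37 (2.18 to 2.57), Ndufa1 2.20 and Ndufa4 2.12. Their median of 1.48 lay at percentile 100 in both kinds of random list, but length-matched random lists themselves centred on 0.88. Neurofilament and large-axon genes had a median of 1.11, with Pvalb at 2.85 (2.59 to 3.13), Spp1 at 2.04 and Nefh at 1.69. That list lay at percentile 97.7 once length was matched. Synaptic vesicle genes had a median of 0.50 (percentile 99.97 among lists matched on length and expression), with Vamp1 at 2.28 (2.11 to 2.46) and Rab3a at 1.64. The higher mitochondrial share of the SNI with brush library stands beside all 3 lists. Genes whose names start with Rpl or Rps, which include the ribosomal protein genes, were higher too. They took 0.293% of all UMIs in the hot water bath library and 0.664% in the SNI with brush library.

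Heat shock and chaperone genes had a median of 0.59, with 9 of 17 at least 1.5-fold higher in the SNI with brush library. Hspe1 had 1.54 (1.34 to 1.74), Hspa8 1.38 (1.29 to 1.47) and Hsp90aa1 1.07 (0.99 to 1.15). The list lay at percentile 99.8 by expression and 79.6 when length was matched. Immediate early genes, which report recent activity, had a median of 0.37 at percentile 59.6 (38.9 with length matched), with Nr4a3 at -1.27 (-2.01 to -0.63) and Nptx2 at 2.33 (1.05 to 4.01). By class, the list had a median of 0.53 at percentile 95.3 in glutamatergic-like nuclei and 0.066 at percentile 16 in inhibitory-like nuclei. Fos gave 53 and 50 UMIs over neurons, a log2 ratio of 0.52 (-0.07 to 1.10), and 33 and 20 UMIs in glutamatergic-like nuclei, with 1.32 (0.43 to 2.15). The axon injury list had a median of 0.10 at percentile 20.9 (11.4 with length matched), or -0.14 under size factors, with Npy at 4.29 (3.56 to 5.24) and the growth-associated Gap43 at -0.96 (-1.04 to -0.88).

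Of 22 neuropeptide genes, 14 were at least 1.5-fold higher in the SNI with brush library and 4 at least 1.5-fold lower, with a median of 1.01. Beside Npy and Nppc, Ucn had 4.01 (2.30 to 7.42) from 2 and 26 UMIs and Nts 3.63. When ratios were averaged over the 2 transmitter classes the median was -0.071. Peptide receptors had a median of 0.47, with Vipr2 at 3.41, Ntsr2 at 2.03 and Cckbr at 2.00. Of the receptors for descending monoamines, Adra1a had -1.36 (-1.50 to -1.23) and Adra1b -0.94 (-1.18 to -0.71), and Htr1d had -1.44, Htr2b -0.91 and Htr4 -0.67. Htr1f was higher at 0.57 (0.49 to 0.66), and Htr3b gave 0 and 25 UMIs, a log2 ratio of at least 3.25 by its interval. The adrenergic and serotonin receptor lists had medians of 0.11 and 0.20, which were -0.13 and -0.04 under size factors. Cholinergic genes had a median of 1.10, with Slc5a7 at 1.53 (1.14 to 1.94), and Slc18a3 gave 0 and 20 UMIs. The acetylcholine synthesis enzyme Chat was level (73 and 46 UMIs, -0.06, -0.63 to 0.49), and within glutamatergic-like nuclei the list median was 0.19.

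Ion channel and receptor lists had medians between -0.18 and 0.32. Voltage-gated sodium channel genes had 0.32 (percentile 97.8, and 97.6 with length matched), with the subunit Scn4b at 2.58 (2.26 to 2.93), and -0.074 when averaged over the 2 classes. Potassium channels had 0.17 (percentiles 93.7 and 96.6), or -0.072 under size factors, with Kcnt1 at 1.41. Calcium and HCN channels had 0.05, or -0.19 under size factors, with Cacna2d3 at 1.21 and Cacna2d1 at -0.61. Ionotropic glutamate receptors had -0.09 with Gria1 at -0.97, GABA-A and glycine receptors -0.18 (percentiles 2.39 and 7.05) with Gabrb1 at -1.01, and cannabinoid and TRP genes -0.02 with Trpc5 at 1.01.

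**Figure D3:**
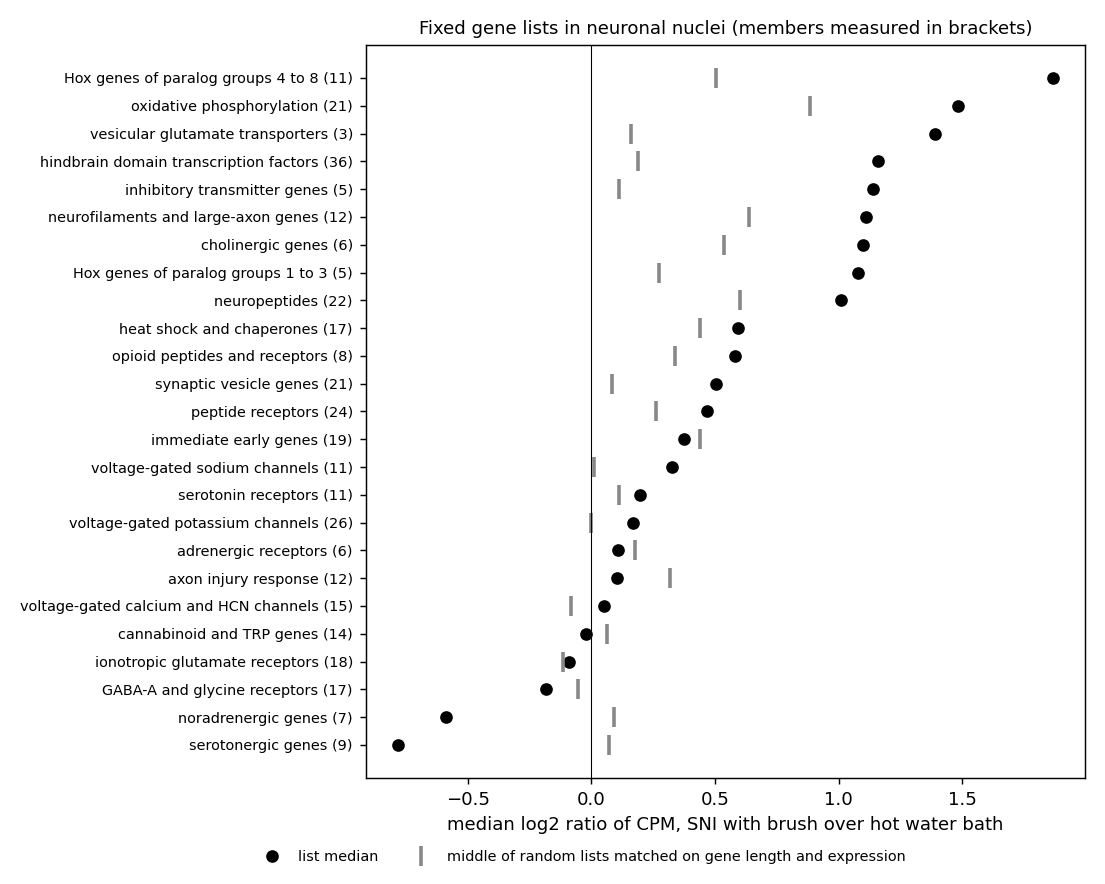
Median log2 ratio of CPM, SNI with brush over hot water bath, for each fixed gene list in neuronal nuclei (black points), with the middle of random lists matched on gene length and expression (grey bars). Hox genes of paralog groups 4 to 8 lie highest at 1.87 and serotonergic genes lowest at -0.78.

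Most marker lists of other cell types had higher medians in the SNI with brush neurons. Ependymal markers had a median log2 ratio of 4.91, with Rarres2 at 0.123 and 8.03 CPM, seen in 2 and 17 neurons. Rarres2 also stood at 60.7 CPM in the liver-gene nuclei, so its level in neurons may include RNA of that source. Alb fell far more steeply, from 3347 CPM in those nuclei to 7.10 CPM in SNI with brush neurons. If both RNAs carried over alike, that source gives only a small part of the Rarres2 level. Tmem212, with 0 UMIs in the liver-gene nuclei, stood at 0.369 and 12.7 CPM, seen in 4 and 14 neurons. Astrocyte markers had 1.61, oligodendrocyte markers 1.31, microglial markers 1.12, oligodendrocyte precursor markers 1.40 and cerebellar granule neuron markers 2.50. The precursor median rests on 3 of 6 markers and the granule neuron median on 4 of 6. Members with too few UMIs to enter included Pdgfra (2 and 6) and Gabra6 (0 and 3), so these medians do not show the named cell types. Among the microglial markers, P2ry12 (-0.06, -0.20 to 0.08) and Cx3cr1 (0.16, -0.20 to 0.52) were level. Markers of V2a-type neurons, a glutamatergic type of the reticular formation, were lower with a median of -0.73.

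The last comparison set glutamatergic-like against inhibitory-like nuclei within each library. Of 49 opioid, receptor and peptide genes, 6 were higher in inhibitory-like nuclei of both libraries with intervals apart: Penk, Pnoc, Sst, Npy, Nts and Gal. Penk stood at 3.88 CPM in glutamatergic-like and 116.5 CPM in inhibitory-like nuclei after the hot water bath, and at 20.3 and 73.9 CPM in the SNI with brush library. Sst stood at 4.62 and 129.4 CPM, and at 39.5 and 185.9 CPM. None was higher in glutamatergic-like nuclei of both libraries by cluster. By each nucleus's own UMIs under the 75% rule, Tac1, Tac2, Crh, Adcyap1 and Htr2a were. Under that rule, whose inhibitory nuclei can include serotonergic ones, 5 genes were higher in inhibitory nuclei of both libraries: Penk, Pnoc, Sst, Npy and Htr2c. Gal and Nts were not among them, with 8.49 and 21.0 CPM in glutamatergic and 2.41 and 4.29 CPM in inhibitory nuclei of the SNI with brush library. Gal had the opposite order in the hot water bath library. With UMIs of one kind only, Pnoc, Sst, Npy and Htr2c were higher in inhibitory nuclei of both libraries, whereas Penk had overlapping intervals in the SNI with brush library (35.3 and 47.8 CPM) and Gal and Cartpt had opposite orders.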

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

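In this part, the tests of the liver-gene nuclei and of the Hox genes were chosen after the results were seen; the predictions of the other tests were written down after the patterns but before the values of those tests were computed. The mitochondrial test of the inhibitory share replaced a test of depth whose result had been seen (Slc6a5 in 27.5% of SNI with brush neurons thinned to 9000 UMIs, against 5.67%), and the shares by cluster among the same nuclei, 13.6% and 6.95%, may have been known by then. The values over all 17 liver-gene nuclei and the counts of single nuclei were added after the others.

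Liver-gene nuclei appeared outside the neuronal comparisons, at 5.94% of kept SNI with brush nuclei (17 of 286) against none in the hot water bath library, above the limit that a count of 0 allows. All 12 genes of a hepatocyte list (chosen after the cluster was seen; 2 of the 12 also exceed 5 CPM in neurons of that library) were present at a summed 13741 CPM, against 21.2 CPM in the neurons, with Cps1 at 3775 and Alb at 3347 CPM. The 8 neuron markers stood at 26.2% of their level in neurons, which is no test of free liver RNA in neuron droplets, because low levels of the same markers had set the cluster apart. Only 11.8% (interval 1.46 to 36.4%) held the neuronal RNA Meg3 at 25% or more of the neuronal median, so most of these nuclei held little neuronal RNA. Meg3 is not among those markers, but a cluster set apart by low neuron markers would tend to be low in it too. Droplets holding a neuron with free liver RNA or with a hepatocyte could lie in neuronal clusters. The Meg3 value therefore does not decide between these explanations. Some liver RNA was present in neuron droplets of that library: Alb was seen in 45 of its 269 neurons, against 0 of 423 hot water bath neurons. The hepatocyte list stood at 0.924 CPM in hot water bath neurons, against the 21.2 CPM given above. These values do not tell free RNA from a hepatocyte in the droplet. Whole nuclei of another tissue, which the sort for the nuclear label should remove, stay open; the design names no biological explanation, and none was tested.

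Higher oxidative phosphorylation and large-axon genes in the SNI with brush library form the second pattern. Nuclei with over 0.5% mitochondrial UMIs are argued against as the whole cause for the oxidative phosphorylation genes, whose median was still 1.26 without them. The nuclei left still differed, with 0.0829% mitochondrial UMIs in 403 hot water bath nuclei and 0.188% in 191 SNI with brush nuclei. A smaller mitochondrial excess therefore stays open, and this test covered the oxidative phosphorylation genes only. Gene length alone is argued against as the whole cause too, as the list lay at percentile 100 of length-matched lists, although those lists centred on 0.88 and so carry part of the size. Free RNA stays open. In the 15 liver-gene nuclei with little Meg3, the large-axon genes stood at 69.3% (59.2 to 80.5%) of the excess between libraries. That lies between the bounds set in advance. In all 17 the value was 101.6% (90.8 to 113.4%), but 150 of the 320 UMIs came from the 2 nuclei rich in Meg3. The oxidative phosphorylation genes stood at 2902 CPM in the 15 and at 2873 CPM in SNI with brush neurons. The liver-gene nuclei may express these genes themselves, so that value cannot decide. A treatment effect stays open and untested, with 1 library per treatment.

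A higher inhibitory share in the SNI with brush library is the third pattern. Free RNA of inhibitory neurons stays open. Gad1, Gad2, Slc32a1 and Slc6a5 together stood at 14.4% (7.88 to 24.2%) of their level in neurons in the 15 liver-gene nuclei with little Meg3. That value is under the bound of 25% but rests on 14 UMIs. In all 17 it was 40.9% (30.5 to 53.8%), with 36 of the 51 UMIs in 1 nucleus rich in Meg3. Inhibitory transmitter genes were also higher in glutamatergic-like nuclei of the SNI with brush library, as free RNA could give. Their median log2 ratio there was 1.38, with 4 of 5 at least 1.5-fold higher. Nuclei with over 0.5% mitochondrial UMIs are argued against as the whole cause of the higher share by own UMIs. Without them that share, which can include serotonergic nuclei, was 34.0% (27.3 to 41.2%) against 19.1% (15.4 to 23.3%) in the hot water bath library. The nuclei left still differed in mitochondrial share, so a smaller excess stays open. A more caudal part of the hindbrain in the pool is a candidate explanation: the Hox genes of paralog groups 4 to 8 had medians above 0 in both classes, the lower being 0.86 at percentile 86.4 from 5 genes, whereas Gcg, a gene of the caudal brainstem, was lower (-3.22). The treatment itself stays open and untested, as does any difference between pools.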

How the results depend on the processing

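The filters on nuclei removed none, so the values without a filter and with at least 1000 genes equal those reported and say nothing about stability. The glutamatergic-like share was higher in the hot water bath library under all 12 alternatives, including those 2, and the serotonergic share under all 10 that give it. The inhibitory-like share was higher in the SNI with brush library under 11 of 12. The exception was resolution 0.5, with 3.31% after the hot water bath and 0.743% in the SNI with brush library, where 28.8% and 78.8% of neurons had no transmitter name. The size of these shares depended on the clustering. At resolution 2.0 the glutamatergic-like and unnamed-transmitter shares of the hot water bath library were 55.3% and 27.9%. With 15 components the inhibitory-like shares were 5.44% and 10.8% and those without a name 23.6% and 67.3%. Without centring, inhibitory-like and unnamed-transmitter nuclei each made up 36.7% of the SNI with brush library. With each library clustered on its own, the hot water bath shares were 52.2% glutamatergic-like, 5.91% inhibitory-like and 34.8% without a name, and the SNI with brush shares 14.9% glutamatergic-like, 0 serotonergic and 61.3% without a name. By nucleus with UMIs of one kind only, the hot water bath shares were 54.6% glutamatergic and 14.4% inhibitory. By the 75% rule, added later, the shares were 59.8% and 19.9% after the hot water bath and 45.7% and 39.0% in the SNI with brush library. In nuclei with at most 0.5% mitochondrial UMIs, added later, inhibitory-like shares were 6.95% and 13.6% and the SNI with brush share without a name was 57.6%. Under the first naming rule the hot water bath share without a name was 14.2%. Apart from the naming rule, whose effect is 1 cluster moved by construction, the cause was not tested.

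Size-factor scaling turned the median log2 ratio over genes to -0.048 in neurons, -0.10 in glutamatergic-like and -0.10 in inhibitory-like nuclei, by construction, and gave median absolute ratios of 0.33 and 0.36 in the classes. Means over nuclei gave medians of 0.21 in neurons and 0.14 in glutamatergic-like nuclei, and absolute medians of 0.38, 0.34 and 0.34 in neurons and the 2 classes. Low-mitochondrial nuclei gave 0.18 and 0.34 in neurons, Scrublet calls kept gave 0.32 (absolute, glutamatergic-like) and 0.092 (inhibitory-like), and the 75% rule gave 0.19 and 0.38 in inhibitory nuclei. Among lists, the noradrenergic median turned to 0.24 with genes of 5 or more UMIs and the hindbrain factors to -0.15 with 100 or more. Averaged over the 2 classes, neuropeptides turned to -0.071 and sodium channels to -0.074. GABA-A and glycine receptors stood at -0.42 under size factors. Leaving out the 2 filters that removed no nucleus, 621 of 720 values for 148 named ratios stayed within the counting interval. A turn of sign was counted only for ratios whose own interval excluded equal levels. By that count 2 values turned, both of Gad2: -0.094 under size factors and -0.19 in low-mitochondrial nuclei. Sign changes of ratios whose interval held equal levels, such as those of Dbh and Slc6a4 under size factors, were not counted. The 621 include 128 values with 2 added UMIs and 144 with Scrublet calls kept, settings that change little. Size factors left 99 of 148 within the interval, and low-mitochondrial nuclei left 103 within it and 24 outside. By nucleus, 5 genes were higher in glutamatergic nuclei of both libraries under each rule (Htr2a only under the 75% rule, Htr1d only with UMIs of one kind), against 0 by cluster. The cause of these was not tested. Depth limits genes with few UMIs, such as Dbh with 13 and 10.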

Other observations

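Serotonergic neuron-like nuclei differed in other genes between the libraries, though the SNI with brush library held only 4, which also carried more mitochondrial RNA (0.867% of UMIs against 0.0651%) and more Gm42418 (1.14% against 0.145%). Slc6a4 stood at 225.5 CPM (200.8 to 252.5) in 30 hot water bath nuclei, where 16 had a UMI, and at 1125 CPM (970 to 1298) in the 4 SNI with brush nuclei. Tac1, a substance P precursor, gave 0 UMIs in the 30 nuclei, which allows up to 2.25 CPM, and 26 UMIs in 2 of the 4. The alpha-1A adrenergic receptor gene Adra1a stood at 551 CPM (512 to 593) in the 30 nuclei and gave 0 UMIs in the 4, which allows up to 18.0 CPM. Gad2 stood at 337 CPM (307 to 370) and 89.8 CPM (50.2 to 148.0).

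Both libraries held nuclei of both sexes. By at least 5 UMIs of Xist or at least 2 UMIs of 4 Y-linked genes, 254 and 139 of 425 hot water bath nuclei, and 146 and 119 of 288 SNI with brush nuclei, held one kind. Both kinds were found in 3 (0.706%, 0.146 to 2.05%) and 5 nuclei (1.74%, 0.566 to 4.00%). Scrublet had called 2 in each library. By the 75% rule the inhibitory share was 19.0% (14.4 to 24.4%) in Xist nuclei and 24.5% (17.6 to 32.5%) in Y-linked nuclei after the hot water bath, and 40.7% (32.6 to 49.2%) and 33.7% (24.7 to 43.6%) in the SNI with brush library. The glutamatergic share by that rule was 65.1% and 46.2% in Xist nuclei of the 2 libraries. In Y-linked nuclei it was 46.8% (38.3 to 55.4%) and 49.0% (39.1 to 59.0%), without the difference seen over all neurons. By cluster, 58.3% and 33.7% of Y-linked nuclei were glutamatergic-like.

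The median log2 ratio over neurons declined with gene length, with 0.64, 0.42, 0.27, 0.11 and -0.05 over 5 equal groups of genes from the shortest to the longest.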
